A study of Micropterus dolomieu and Micropterus salmoides with 32 samples.

How the data were processed

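Adult smallmouth bass of 4 treatments were sampled for gill and liver, per the labels, giving 32 arrays of 16 fish. Per the labels, total RNA was labelled with a two-colour kit, the sample with Cy5 and a pooled male liver reference of Micropterus salmoides with Cy3. The labels list both bass species for the sample channel, and the species follows the series title. No dyes were swapped, so a dye bias of a probe is the same on every array and drops out of differences between groups. Per the file headers, the arrays were read with Feature Extraction 10.1.1.1.

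The deposited scanner files hold 45220 spots per array, of which 1417 are control spots, with mean and background intensity per channel on a linear scale. They also hold the scanner's log10 ratio of processed red to green signal and flags for spots that are outliers, saturated or well above background, per the file headers. The deposited value table of the series holds the authors' processed log2 ratios of the same arrays, with 29130 rows that match the probe names. Set against the scanner's ratios converted to log2, its differences between arrays had a slope of 0.992 in liver (r = 0.990) and 0.978 in gill (r = 0.959). So its scale and direction are known. In liver 100% of its rows had a median of 0 over the 16 arrays, within 0.0001, and in gill 0.0206% did, so liver rows were centred and gill rows were not. Column medians lay between -0.01 and 0.02 in liver and between -0.004 and 0.07 in gill. How those values were normalized is not given in the sources used here. The gill minus liver level could not be taken from that table.

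Mean intensities were background-corrected with normexp and an offset of 50, which pulls ratios of dim probes towards 0, and normalized within each array by loess with control and outlier spots at weight 0, using limma 3.58.1 in R 4.3.3. Control spots and outlier-flagged spots were then left out, and the 2 spots of a probe were averaged (14673 probes were printed on 2 spots and 14457 on 1). A probe was tested in a tissue if its Cy5 signal was well above background on at least 4 of the 16 arrays. For differences between tissues at least 4 of the 32 arrays were required. The 29130 probes held 29118 distinct sequences. Over 8 tested pairs of probes with the same sequence, the estradiol effects in liver differed by a median of 0.02 log2 units. Probes sharing a stretch of 20 bases or more were taken as one when probes were named. Some transcripts are covered by several probes, and the counts are of probes.

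For each tissue limma's lmFit and eBayes were fitted over the 16 arrays and 4 groups, without covariates, and the contrasts were treatment differences, the interaction of estradiol and bacteria, and sex adjusted for treatment. Gill and liver were compared on the gill minus liver difference of each fish, and the tests are two-sided. P-values were adjusted by Benjamini-Hochberg over the probes tested in a contrast, with a threshold of 0.05. The tests, samples and most alternatives were fixed before the data were examined. Each fish is a biological replicate per the series design. The fits were tested on simulated data with 200 changed probes per comparison, at log2 changes of 0.5, 1 and 2. For estradiol against control these were recovered at 20.9%, 70.1% and 84.8% in liver and 25.4%, 82.1% and 100% in gill. For the interaction the shares were 4.48%, 43.3% and 74.2% in liver and 7.46%, 47.8% and 95.5% in gill, and for sex 43.3%, 76.1% and 95.5% in liver and 56.7%, 89.6% and 100% in gill. For gill against liver they were 77.6%, 94.0% and 100%, and for the difference of the estradiol effect between tissues 1.49%, 47.8% and 86.4%. Up to 7.22% of the probes passing in the simulated data were false. The simulation drew each probe independently, without deviations that probes of one array share. It also held 200 changed probes, and with fewer changed probes the adjustment asks for a smaller p, so a smaller share would be recovered. So these shares may not hold for the real arrays.

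The files used here carry no gene names or descriptions for the probes, and the genome coordinates of the probes are not known here. The gene lists fixed beforehand, for estrogen response, immune response and cell types, could therefore not be matched to probes and were not tested. The rule fixed for named genes took named probes past the threshold with all 4 treated arrays on the same side of the comparison mean, largest changes first, and so named none. The same rule without the name, and limited to 2 rises and 2 falls per comparison, was chosen after the values were seen and gave the probes reported. For differences between tissues the condition was that all 16 fish agreed, which passed over EA_Msa_UN_111912 (-11.87, the largest fall), as 1 fish had no value for it and the other 15 agreed. No condition was set for differences of effects.

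Slide and scan session were taken from the file headers. Each of 8 slides held 4 arrays, 1 of each treatment, from 1 tissue, and the replicate number of the labels is the same as the slide. With 1 array per treatment on a slide no test within a slide is possible, so the shares of probes with the same direction on every slide are given, and slide was fitted as a block. As those probes were chosen on the same arrays, each slide was also left out of the fit in turn and the direction read on it, a check added after the data were seen. Alternatives were the scanner's log ratios, the Cy5 signal alone after quantile normalization, no filter on dim probes, the replicate number or slide as a block, sex as a covariate, a fit over all 32 arrays with fish as a random block, the deposited value table, and leaving out each array or fish. Array weights, and leaving out 2 gill arrays that stand apart, were added after the data were seen. Effects of estradiol and bacteria over all fish of a tissue were also added then.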

Results

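Gill and liver RNA of 16 adult smallmouth bass (Micropterus dolomieu) was profiled on 32 two-colour oligonucleotide arrays, 1 array per tissue of each fish. The labels name 4 treatments: control, estradiol, bacteria, and bacteria together with estradiol. Estradiol is the main estrogen of vertebrates. The labels do not name the bacterium, the doses or the time of sampling. Each treatment held 4 fish, 2 females and 2 males, and both tissues of a fish carry the same identifier. On every array the Cy5 channel held the sample and the Cy3 channel held one common reference, a pool of livers from male largemouth bass (Micropterus salmoides). Values are therefore log2 ratios of sample to reference. Of 29130 probes of 60 bases, 21358 were tested in liver and 20711 in gill.

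The median background-subtracted Cy5 intensity lay between 38.3 and 110.0 in liver and between 57.0 and 153.4 in gill. Between 47.6% and 76.8% of probes were well above background in Cy5 on the liver arrays, and between 58.5% and 75.8% on the gill arrays. The dimmest liver array was control replicate 2. Its median rank correlation with the other livers of its group was 0.497, against 0.749 to 0.882 for the other 15 liver arrays with theirs. The highest correlation between any 2 arrays was 0.979, so no array was a copy of another. The number of arrays limits the precision, 4 per group. No table pairing probes with genes was used here, so probes are given by their identifiers and sequences.

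The first comparison asked what estradiol changed in liver. Estradiol moved 1464 of 21358 liver probes (6.86%), of which 779 were higher and 685 lower than in control livers, with limma and a Benjamini-Hochberg adjusted p under 0.05. Many changes were large. Of these probes, 483 rose and 481 fell at least 2-fold, and 87 rose and 36 fell at least 8-fold. The largest rise was of EA_Mdo_AF_100073 (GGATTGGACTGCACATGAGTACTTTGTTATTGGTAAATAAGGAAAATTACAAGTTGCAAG), whose log2 ratio was 1.26 ± 2.90 (SD, n = 4) in control livers and 10.6 ± 1.81 in estradiol livers. It rose by 9.34 on the log2 scale (SE 1.40, adjusted p = 0.000733, limma) and was well above background on 2 of the 4 control arrays. Control replicate 3 read 5.55 for it and the other controls -0.60 to 0.49. Without that array the rise was 10.77, over 3 controls of which 1 was well above background, so its size is uncertain. EA_Msa_UN_118898 (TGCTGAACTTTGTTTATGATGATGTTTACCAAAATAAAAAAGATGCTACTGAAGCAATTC) went from 0.40 ± 2.06 to 8.65 ± 1.45, a rise of 8.24 (SE 1.1, adjusted p = 0.000291, limma), and was also well above background on 2 of the 4 control arrays. Its rise also depended on control replicate 3, which read 3.49 against -0.75 to -0.44 in the others, and was 9.27 without it, again over 1 control well above background.

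The largest fall in the same comparison was of EA_Msa_UN_113001 (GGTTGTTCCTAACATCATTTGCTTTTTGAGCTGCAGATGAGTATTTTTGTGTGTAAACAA). Its log2 ratio was 1.09 ± 1.16 in control and -4.95 ± 0.66 in estradiol livers, a change of -6.03 (SE 0.57, adjusted p = 1.9e-05, limma). EA_Msa_UN_117489 (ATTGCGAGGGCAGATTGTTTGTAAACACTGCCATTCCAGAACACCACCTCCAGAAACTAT) went from 1.39 ± 0.70 to -3.54 ± 0.65, a change of -4.94 (SE 0.48, adjusted p = 2.24e-05, limma). Within the 4 slides, each holding 1 array per treatment, 1402 of the 1464 probes (95.8%) differed in the same direction on every slide, though they were chosen on these arrays. When each slide was left out of the fit in turn, between 80.2% and 99.2% of the probes passing on the other 3 slides differed in the same direction on the slide left out. With no effect 50% would follow on average. Each share rests on 1 array per group, and its probes are not independent replicates, so a single slide can lie far from 50% by chance. The count was 894 without estradiol replicate 2 and 2279 without estradiol replicate 4. It was 2457 with the scanner's own log ratios, 2491 with the authors' deposited value table, 2467 in a fit over both tissues and 4570 with arrays weighted by quality, an alternative added after the data were seen.

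**Figure D1:**
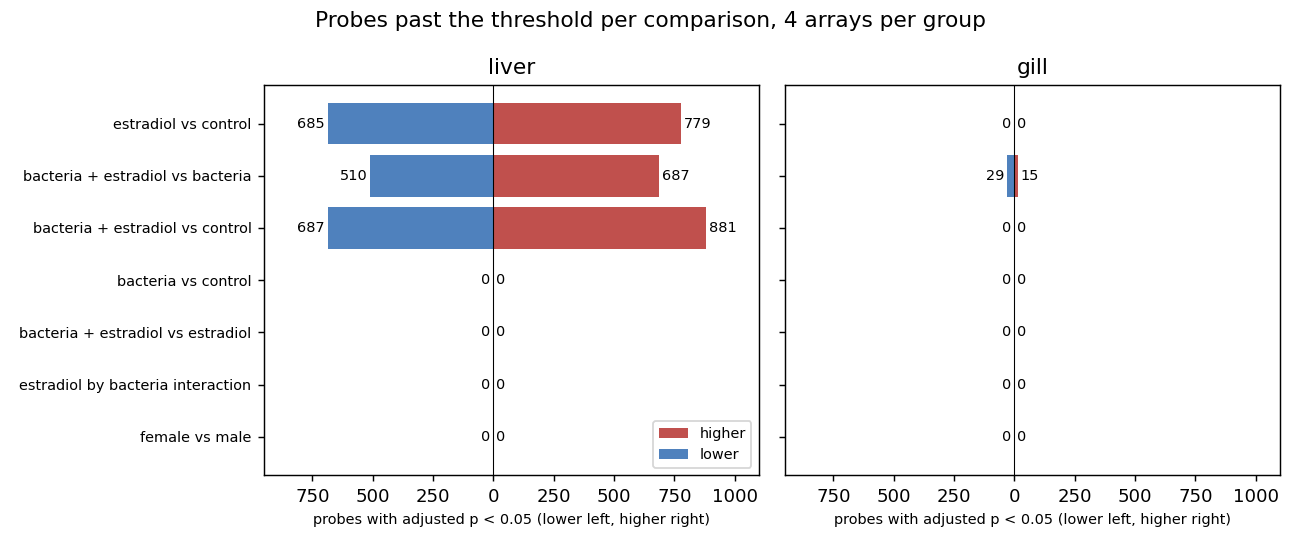
Number of probes with a limma adjusted p under 0.05 in each comparison, in liver (left) and gill (right), with probes higher in the first-named group to the right of 0 and lower probes to the left. Counts stand beside the bars, each group held 4 arrays (8 per sex), and the 3 liver comparisons that differ in estradiol hold 1464, 1197 and 1568 probes.

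The same question was put to fish that also received bacteria. In liver, estradiol together with bacteria moved 1197 probes relative to bacteria alone, 687 higher and 510 lower, and 441 of the rises and 347 of the falls reached 2-fold. EA_Mdo_AF_100073 again had the largest rise, from 1.78 ± 2.54 (SD, n = 4) to 11.03 ± 0.69, or 9.25 (SE 1.40, adjusted p = 0.00104, limma). Bacteria replicate 3 read 5.15 for it and the other bacteria livers -0.28 to 2.32. Over 25 refits its rise ran from 8.56 to 10.55, so its size is uncertain. EA_Msa_UN_118898 rose by 8.51 (SE 1.1, adjusted p = 0.00031, limma) and was well above background on 3 of the 4 arrays with bacteria alone. Bacteria replicate 3 read 2.32 for EA_Msa_UN_118898 against -1.58 to 0.07 in the others, and its rise ran from 8.01 to 11.31 over the refits. The largest falls were of EA_Msa_AF_100767 (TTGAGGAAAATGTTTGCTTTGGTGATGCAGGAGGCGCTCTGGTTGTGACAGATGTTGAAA), from 0.98 ± 0.95 to -4.79 ± 1.09, and of EA_Msa_AF_100343 (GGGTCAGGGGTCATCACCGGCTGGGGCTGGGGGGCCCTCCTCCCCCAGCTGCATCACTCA), from 0.22 ± 1.00 to -4.88 ± 0.85. Their changes were -5.77 (SE 0.80, adjusted p = 0.000557, limma) and -5.09 (SE 0.73, adjusted p = 0.000651, limma). On slides left out of the fit in turn, between 92.9% and 99.7% of the probes passing on the other 3 slides differed in the same direction, and of the 1197 probes, chosen on all slides, 1181 (98.7%) did so on every slide. Without bacteria replicate 1 the count was 779, without replicate 4 of the combined treatment it was 777, in a fit over both tissues it was 2027, and with arrays weighted by quality it was 3726.

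These estradiol effects without and with bacteria were measured on separate fish and arrays, so they share no control. Across 21358 probes the fold changes correlated with a Pearson r of 0.846, over probes that are not independent replicates. Of the probes past the threshold, 850 were past it in both comparisons, 480 higher in both, 370 lower in both and 0 in opposite directions. Independent lists of these lengths would share 25.1 higher and 16.4 lower probes. These lists are not independent, since both comparisons use one estimate of the spread per probe and lie on the same slides. Probes with a small spread can pass in both, so these numbers are only a rough reference. Among the 1811 probes past the threshold in either comparison, 1792 (98.95%) had the same sign in both.

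**Figure D2:**
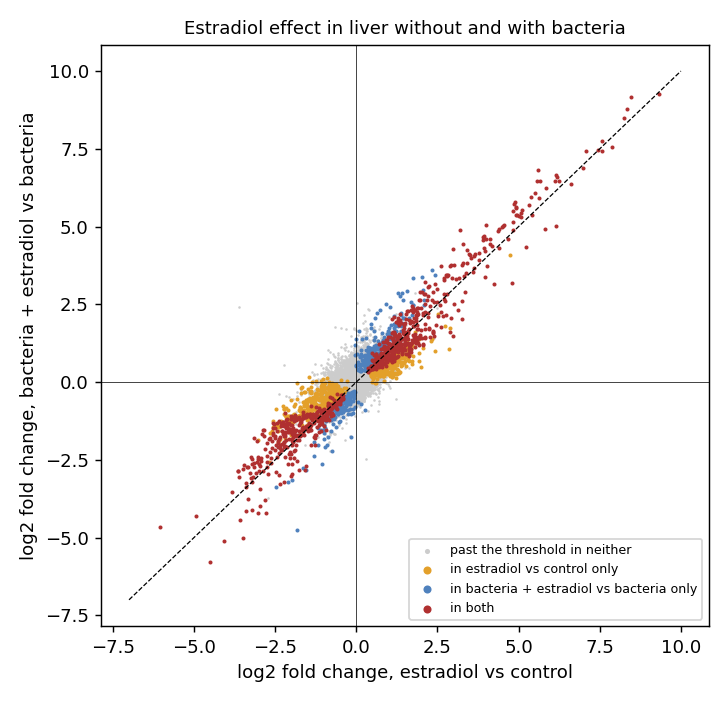
Log2 fold change of each of 21358 liver probes for estradiol against control (x axis) and for bacteria with estradiol against bacteria (y axis), 4 arrays per group. Colours mark probes past the threshold in neither, one or both comparisons, the dashed line marks equal effects, and the 850 probes past it in both lie in the lower left and upper right quadrants.

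Whether the size of the estradiol effect differed with bacteria was tested as an interaction. No liver probe passed (0 of 21358, limma), and 492 had an unadjusted p under 0.05 where 1068 would be expected by chance. The median standard error of this difference was 0.26 on the log2 scale. In simulated data for this comparison, over 21358 probes, 43.3% of differences of 1 log2 unit and 74.2% of differences of 2 were recovered, so differences near 2-fold could be missed. The interaction of EA_Mdo_AF_100073 was -0.09 (SE 1.99, adjusted p = 0.999, limma) and that of EA_Msa_UN_113001 was 1.39 (SE 0.81, adjusted p = 0.999).

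Against control livers, bacteria with estradiol moved 1568 probes, 881 higher and 687 lower, and 540 rises and 476 falls reached 2-fold. EA_Mdo_AF_100073 rose by 9.76 (SE 1.40, adjusted p = 0.000514, limma) and EA_Msa_UN_118898 by 8.00 (SE 1.1, adjusted p = 0.000367). Against the same controls, well above background on 2 of 4 arrays for these 2 probes, the sizes are as uncertain, and without control replicate 3 they were 11.19 and 9.03. EA_Msa_UN_113001 changed by -5.42 (SE 0.57, adjusted p = 4.37e-05) and EA_Msa_UN_117489 by -5.00 (SE 0.48, adjusted p = 2.21e-05). On slides left out of the fit in turn, between 75.4% and 99.1% of the probes passing on the other 3 slides differed in the same direction, the lowest share on slide 2. The count was 1023 without replicate 4 of the combined treatment, 2509 in a fit over both tissues and 3429 with arrays weighted by quality.

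Bacteria alone gave no liver probe past the threshold. In limma, 0 of 21358 probes passed for bacteria against control, with 1162 at an unadjusted p under 0.05 against 1068 expected by chance. For bacteria with estradiol against estradiol, 0 passed and 77 had an unadjusted p under 0.05, where 1068 would again be expected. All 16 livers share one estimate of the spread, so control replicate 2, which stood apart, also entered comparisons without controls. Without it, bacteria with estradiol gave 1745 probes against bacteria in place of 1197, and still 0 against estradiol. So these counts of 0 do not exclude a bacterial effect. Among the probes with the largest estradiol effects, EA_Mdo_AF_100073 differed by 0.52 (SE 1.40, adjusted p = 0.940, limma) between bacteria and control, and EA_Msa_UN_113001 by -0.78 (SE 0.57, adjusted p = 0.869). The median standard error was 0.18 for both comparisons. Without bacteria replicate 2, 30 probes passed for bacteria against control, and 9 passed with arrays weighted by quality.

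In gill, the tissue named in the series title, responses were smaller. Bacteria with estradiol moved 44 of 20711 probes relative to bacteria alone (0.212%), 15 higher and 29 lower, with 7 rises and 15 falls of at least 2-fold. EA_Msa_AF_100107 (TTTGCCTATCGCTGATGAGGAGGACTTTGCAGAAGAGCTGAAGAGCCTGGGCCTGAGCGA) rose most, from -2.54 ± 0.34 (SD, n = 4) to -0.78 ± 0.24, or by 1.76 (SE 0.20, adjusted p = 0.00202, limma). EA_Msa_AF_101388 (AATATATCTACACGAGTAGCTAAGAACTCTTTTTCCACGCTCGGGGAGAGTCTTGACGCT) rose by 1.51 (SE 0.22, adjusted p = 0.007, limma). Both also rose in liver in the same comparison, by 2.46 (SE 0.32, adjusted p = 0.000301) and by 2.84 (SE 0.34, adjusted p = 0.000169). EA_Msa_AF_104254 (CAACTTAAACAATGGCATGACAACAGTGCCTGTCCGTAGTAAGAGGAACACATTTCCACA) fell from 1.06 ± 0.28 to -0.86 ± 0.51, a change of -1.91 (SE 0.27, adjusted p = 0.00649, limma), and EA_Msa_UN_113282 (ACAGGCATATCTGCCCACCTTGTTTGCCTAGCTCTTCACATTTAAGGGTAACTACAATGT) changed by -1.77 (SE 0.32, adjusted p = 0.0274, limma). In gill, bacteria alone lay above control for these 2 probes, by 1.02 and 0.97 (adjusted p = 0.993 for each, limma). Against gill controls the combined treatment changed them by -0.89 (adjusted p = 0.218) and -0.80 (adjusted p = 0.276), so the falls also hold the higher level with bacteria alone. In liver these 2 probes differed by 0.03 (SE 0.26, adjusted p = 0.987) and -0.04 (SE 0.24, adjusted p = 0.984) in the comparison with bacteria alone. Between estradiol and control they differed there by -0.86 (SE 0.26, adjusted p = 0.0615) and -0.97 (SE 0.24, adjusted p = 0.0215).

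Of the 35 ways to part these 8 gill arrays into 4 and 4, 2 gave at least 44 probes, the other one 150, so chance as the source of the count was not excluded. All 44 probes differed in the same direction on each of the 4 slides, but they were chosen on these arrays. Without slide 4, 142 probes passed on the other 3 slides and 80 of them (56.3%) differed in the same direction on slide 4. With no effect 50% would follow on average, and a single slide can lie far from it by chance. Without slide 2, 7 passed and all 7 did so, and without slide 1 or slide 3, 0 passed (limma). With slide, which is the same as the replicate number, as a block, 29 passed, and EA_Msa_UN_113282 was then at an adjusted p of 0.0514 (limma). That probe also lost its call when 1 array was left out: at an adjusted p of 0.106, 0.130 and 0.0510 without bacteria replicates 1, 3 and 4, and of 0.0853, 0.130 and 0.05 without replicates 1, 2 and 3 of the combined treatment. Of the 44 probes, 34.1% were higher, against 50.0% of 10 probes with the scanner's log ratios and 53.8% of 13 with the authors' deposited value table. In a fit over both tissues 66.7% of 33 probes were higher, and without gill control replicate 4 and gill bacteria replicate 2, a choice made after the data were seen, 19.6% of 56. The count was 21 without bacteria replicate 1, 15 without bacteria replicate 3, 83 without bacteria replicate 4, and 28, 17 and 101 without replicates 1, 2 and 4 of the combined treatment. With arrays weighted by quality it was 227. Of 43 of these probes also tested in liver, 10 passed there, 7 higher in both tissues and 3 lower in both, where independent lists would share 0.502 and 0.671. Both lists compare the same fish, so a chance difference between those fish could appear in both tissues. The overlap is therefore no independent test of the gill probes. Probes that read at least 2-fold higher in liver than in gill, over all fish including those with estradiol, made up 9 of the 15 higher and 6 of the 29 lower probes, against 10.8% of all gill probes tested. A rise with estradiol in liver, seen for 7 of the higher probes, can itself place a probe in that class.

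**Figure D3:**
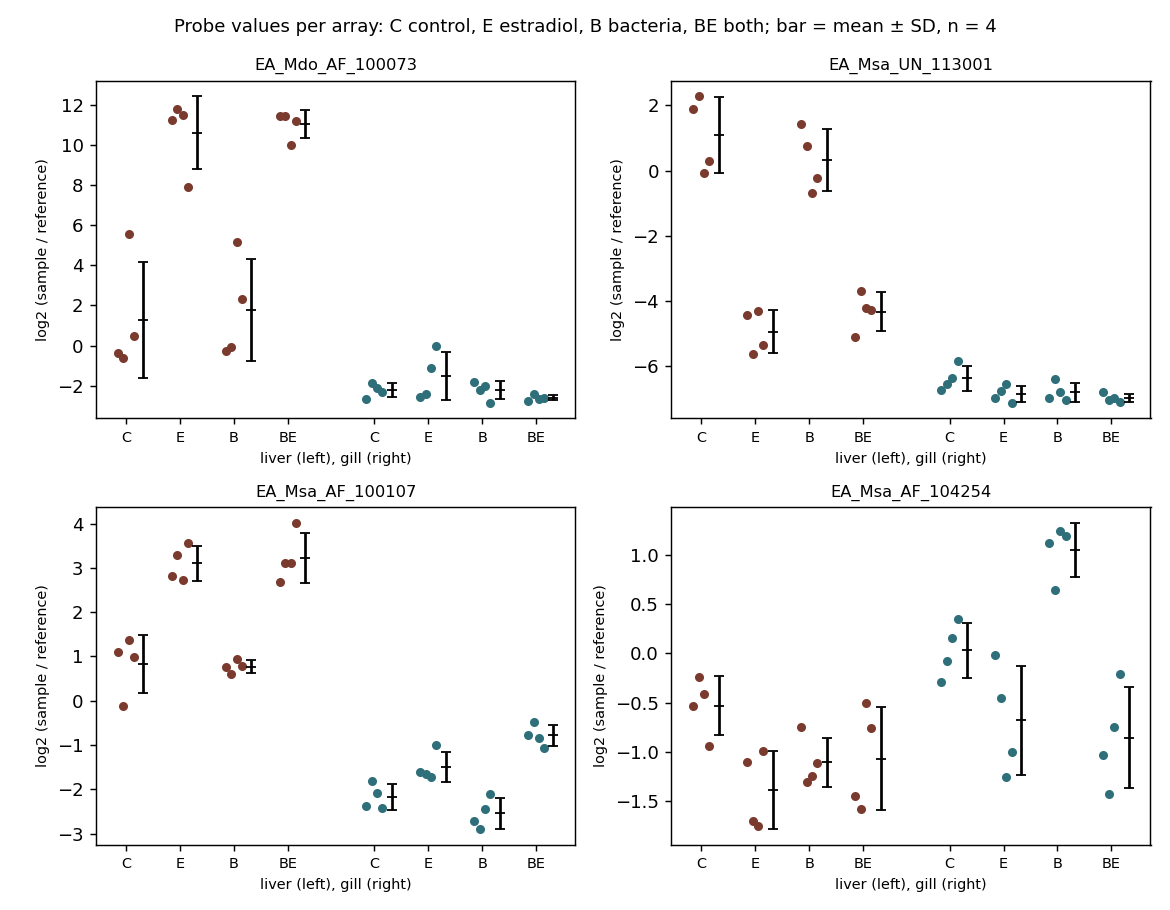
Log2 ratio of sample to reference per array (points) for 4 probes, in liver (brown, left of each panel) and gill (blue-green, right), with the mean ± SD of 4 arrays beside them. EA_Mdo_AF_100073 exceeds 7 on all 8 liver arrays with estradiol and EA_Msa_UN_113001 lies below -3 on them, while EA_Msa_AF_100107 and EA_Msa_AF_104254 are the gill probes with the largest rise and fall between bacteria with estradiol and bacteria.

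No gill probe passed in the remaining treatment comparisons with limma. For estradiol against control, 0 of 20711 passed and 892 had an unadjusted p under 0.05, where 1036 would be expected by chance. For bacteria against control these numbers were 0 and 763, for bacteria with estradiol against estradiol 0 and 1073, and for the interaction 0 and 805. For bacteria with estradiol against control 0 passed while 2949 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0577, that of EA_Msa_AF_100107 (log2 change 1.39, SE 0.20). That last count was 4 without control replicate 1, 10 without estradiol replicate 4, 18 without replicate 4 of the combined treatment, and 1 without control replicate 2, without bacteria replicate 2 and without bacteria replicate 4. It was 38 with arrays weighted by quality, 3 with Cy5 signal alone, 1 with sex as a covariate and 1 in a fit over both tissues. For bacteria against control, 1 probe passed without control replicate 3. In simulated data for estradiol against control in gill, over 20711 probes, 82.1% of changes of 1 log2 unit and 25.4% of changes of 0.5 were recovered.

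Whether the treatments acted differently in the tissues was tested on the gill minus liver difference of each fish. The effect of estradiol differed between gill and liver for 791 of 23926 probes, 313 with a more positive effect in gill and 478 with a more positive effect in liver. Bacteria with estradiol against control also gave 791 probes, 271 and 520 in these directions, and bacteria against control gave 0, with 885 at an unadjusted p under 0.05 (limma). The effect of estradiol was lower in gill for EA_Msa_UN_118679 (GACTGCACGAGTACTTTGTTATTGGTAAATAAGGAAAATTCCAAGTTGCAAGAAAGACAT), which shares a stretch of over 20 bases with EA_Mdo_AF_100073 (adjusted p = 0.000128, limma), and for EA_Msa_UN_118898 (adjusted p = 0.000488). These 2 probes were well above background on 1 and 2 of the 16 gill arrays, and on 0 of the 4 gill controls, so no size is given for the difference. For EA_Msa_UN_113001 and EA_Msa_UN_117489, which fell in liver and were well above background on all gill arrays, the difference was 5.55 (SE 0.63, adjusted p = 0.000135) and 4.69 (SE 0.49, adjusted p = 6.11e-05). In gill controls these probes read -6.38 and -5.15, against 1.09 and 1.39 in liver controls, so they were low in gill without estradiol too. For the combined treatment the effect on EA_Msa_UN_113001 differed by 4.81 (SE 0.63, adjusted p = 0.000444). The effect on EA_Mdo_AF_100073, well above background on 5 of the 16 gill arrays and 0 of the 4 gill controls, was lower in gill (adjusted p = 0.00149). The count of 791 for estradiol was 410 without estradiol replicate 2, and that for the combined treatment was 447 without its replicate 4. For the combined treatment 34.3% of probes were more positive in gill, against 47.6% with Cy5 signal alone.

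Across tissues, the 727 probes that rose with estradiol in liver and were also tested in gill had a median gill log2 change of 0.00, and the 633 that fell had a median of -0.18. The liver and gill fold changes for estradiol against control correlated with a Pearson r of 0.188 across 18778 probes, which are not independent replicates. Over 421 of the liver probes that estradiol lowered, chosen after the data were seen, the median log2 ratio was -5.12 ± 0.18 (SD, n = 8) in gills of estradiol fish and -4.88 ± 0.29 in the other gills (p = 0.0720, exact permutation test, two-sided, or p = 0.0463 permuting within slides). The slides differed by -0.08, -0.49, 0.02 and -0.41, so slide 3 did not share the direction. As many liver-type probes that estradiol did not change in liver also differed, by -0.23 (p = 0.0233, exact permutation test, two-sided, or p = 0.0108 within slides).

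**Figure D4:**
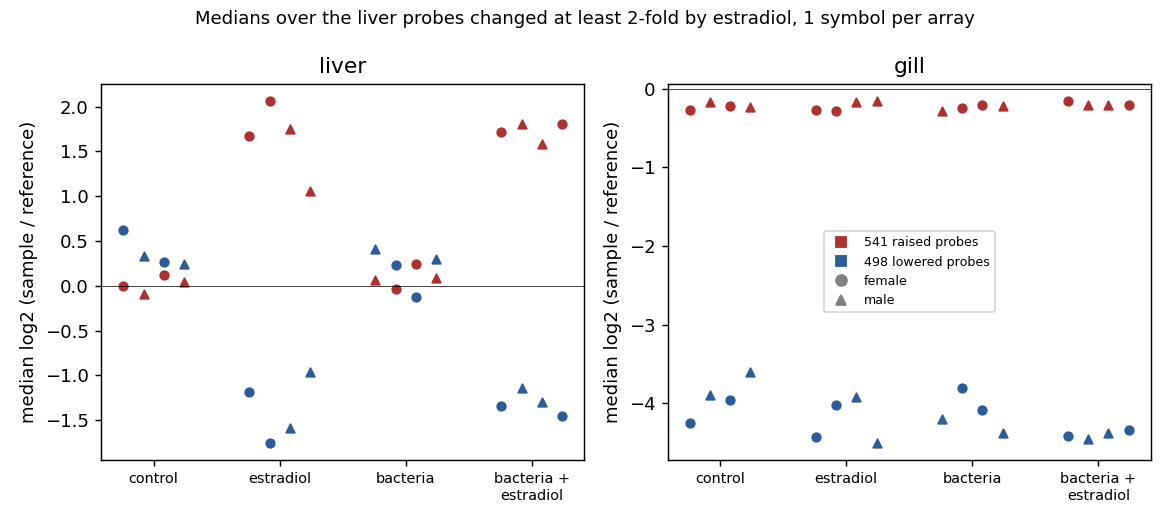
Median log2 ratio per array over the 541 liver probes raised (red) and the 498 lowered (blue) at least 2-fold by estradiol over both bacterial conditions, in liver (left) and gill (right), circles for females and triangles for males. In liver the raised set lies between 1.06 and 2.07 on the 8 estradiol arrays and between -0.10 and 0.25 on the other 8, and in gill it lies between -0.28 and -0.15 on all 16. The sets were chosen on these liver arrays, so their separation in liver is no independent test.

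The tissues themselves differed most. Of 23926 probes, 15584 (65.1%) differed between gill and liver of the same fish, 7420 higher in gill and 8164 higher in liver, with 2070 and 2463 of them at least 2-fold. Which side held more probes depended on the scaling: 9290 were higher in gill and 7355 in liver with the scanner's log ratios, and 9188 and 8827 with Cy5 signal alone. EA_Mdo_AF_100102 (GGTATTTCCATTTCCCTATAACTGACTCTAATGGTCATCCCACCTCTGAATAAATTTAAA) had a log2 ratio of 2.44 ± 0.49 (SD, n = 16) in liver and -8.66 ± 0.27 in gill, a difference of -11.11 (SE 0.09, adjusted p = 2.01e-19, limma). EA_Msa_AF_101621 (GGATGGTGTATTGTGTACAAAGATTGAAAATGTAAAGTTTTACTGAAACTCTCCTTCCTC) differed by -10.69 (SE 0.14, adjusted p = 1.53e-17). In gill, EA_Msa_AF_103863 (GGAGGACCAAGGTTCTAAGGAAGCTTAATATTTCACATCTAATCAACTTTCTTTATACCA) was higher (adjusted p = 2.56e-18), and no size is given, as it was well above background on only 2 of the 16 liver arrays. EA_Msa_AF_102261 (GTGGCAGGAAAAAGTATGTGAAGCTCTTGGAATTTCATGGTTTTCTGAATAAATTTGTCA) was higher by 6.36 (SE 0.15, adjusted p = 5.39e-15). Over 21 refits with other processing or 1 fish left out, the rise of EA_Msa_AF_102261 ran from 4.57 to 9.54. Its SE does not cover that range, so its size is uncertain. Over the same refits the difference of EA_Mdo_AF_100102 ran from -11.16 to -9.31 and that of EA_Msa_AF_101621 from -11.65 to -9.535. The SEs of these probes do not cover their ranges either. All gill arrays were scanned in 1 session and all liver arrays in another, so tissue and scan session cannot be told apart here.

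Females and males were compared within treatments. No probe passed in liver (0 of 21358, limma, 562 at an unadjusted p under 0.05) or in gill (0 of 20711, 474 at an unadjusted p under 0.05). The female minus male difference of EA_Mdo_AF_100073 in liver, 1.65 (SE 0.92, adjusted p = 0.938, limma), did not pass. The females control replicate 3 and bacteria replicate 3 read 5.55 and 5.15 for it, against -0.60 to 2.32 in the other livers without estradiol. In simulated data for this comparison, 76.1% of differences of 1 log2 unit were recovered in liver over 21358 probes and 89.6% in gill over 20711 probes.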

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

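The tests on liver control replicate 2 and of an exchanged sample were written before their results were seen. Those on lowered probes in gill, of other splits of the samples, of sex and of carried-over RNA were chosen after the results they bear on. Of 136 groups of 4 arrays examined for a value far from the other 3, 8 were marked, and chance alone would mark about 6.80.

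In livers without estradiol, control replicate 3 read 3.49 for EA_Msa_UN_118898 and 2.79 for EA_Msa_UN_118679, where the other controls lay between -0.75 and -0.44 and between -0.97 and -0.79. Bacteria replicate 3 read 2.32 and 2.21 for these probes and 5.15 for EA_Mdo_AF_100073, where control replicate 3 read 5.55. Both fish are female, and both arrays lie on one slide with replicate 3 of both estradiol treatments, so a cause shared by that slide stays open too. Over the 20 probes that estradiol raised most, these 2 livers lay 2.52 and 2.19 above the other 3 of their groups. Their median log2 ratios were 2.27 and 1.85, against -0.26 to 0.08 in the other livers without estradiol. For EA_Mdo_AF_100073 alone, bacteria replicate 4, a male, read 2.32, above the -0.28 and -0.08 of bacteria replicates 1 and 2. An exchange with an estradiol sample was not seen, since the lowest estradiol liver lay 1.65 above the highest of the others on the raised minus lowered probes. Those probes were chosen on the same arrays under the same labels, which favours such a gap, so this is no independent test. RNA carried over from an estradiol liver would leave the lowered probes in place. In bacteria replicate 3 these lay 0.53 below the group (a deviation of -0.53, against -0.19 to 0.29 in the livers other than these 2), which argues against it there, while in control replicate 3 the deviation of -0.19 leaves it open. On the raised minus lowered probes, the 4 females without estradiol scored -0.17 ± 0.42 (SD, n = 4) and the 4 males -0.30 ± 0.11 (p = 0.657, exact permutation test, two-sided). Control replicate 3 scored -0.15 there, near the -0.21 of the highest male, so this score barely holds the pattern seen in the most raised probes. The test therefore cannot decide on sex, which is not shown to be the cause. A state of single females may be the cause and was not measured.

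Liver control replicate 2 stood apart from the other livers and was the dimmest in Cy5. Low signal alone is argued against: over the brightest 25% of probes, the median absolute deviation of its differences from the other controls was 1.1, against at most 0.559 on the other 15 liver arrays. RNA of gill is argued against by the 200 most gill-enriched probes, which lay 0.22 above the other controls, within the range of -0.61 to 1.11 of the other liver arrays. Its cause stays open, and a difference of the fish itself was not tested.

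The liver probes that estradiol lowered read lower in gills of estradiol fish by 0.24 log2 units (a difference of -0.24, p = 0.0720, exact permutation test, 8 against 8, or p = 0.0463 permuting within slides, with 0.02 on slide 3 and -0.49 to -0.08 on the others). As many liver-enriched probes that estradiol did not change in liver differed by -0.23 (p = 0.0233, exact permutation test, or p = 0.0108 within slides), so a shift of liver-type probes on these arrays could account for it. The lowered minus the matched probes gave p = 0.900 (exact permutation test, or p = 0.920 within slides), so an estradiol effect in gill cannot be told apart from that shift. The match on gill level was partial, with medians of -5.06 and -3.21. These tests replaced 2 planned ones once their values were seen. The planned ones concerned gill of estradiol replicate 4, where the 20 probes that estradiol raised most in liver deviated by 0.44, above the 0.35 of the highest other gill. Liver-type probes deviated there by -0.30, within the -0.41 to 0.47 of the other gills. The raised minus lowered score was 4.07 ± 0.22 (SD) in the other 7 estradiol gills against 3.79 ± 0.25 in 8 without (p = 0.0437, exact permutation test). That score met the bound set for an estradiol effect before the shift of liver-type probes was looked at.

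Estradiol replicate 4 had the narrowest log2 ratios of the estradiol livers, with an SD of 0.545 against 0.899 to 0.947, and read 7.90 for EA_Mdo_AF_100073 against 11.25 to 11.78. Replicate 3 of the combined treatment read 10.0 in liver for that probe against 11.21 to 11.45. In gill, replicate 1 of the combined treatment had a median of -0.16 over the estradiol-raised liver probes against -0.21 to -0.20, bacteria replicate 2 read 0.12 for EA_Msa_UN_113282 against 0.96 to 1.11, and estradiol replicate 3 read 7.50 for EA_Msa_AF_102261 against 6.88 to 6.96.

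The effects of estradiol and of the combined treatment differed between gill and liver by a test of the difference itself, for 791 probes each. Some of these probes may be too dim in gill to show an effect. For these comparisons, other splits of the 8 fish gave at most 35 and 3 probes, and 1 of 35 splits, the real one, reached the real count. No other split reached it. The same held in liver for estradiol against control (1464 probes, at most 753 in the other splits), bacteria with estradiol against control (1568, at most 1) and bacteria with estradiol against bacteria (1197, at most 4). The split with 753 exchanged control replicate 2 and estradiol replicate 4. For gill against liver, 1 of 100 draws of which array is called gill reached 15584 probes, and the others gave at most 11596, since a draw that calls unequal numbers of arrays gill keeps part of the tissue difference.

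For bacteria with estradiol against bacteria in gill, 2 of 35 splits gave as many as 44 probes and the other one gave 150, several times the real count, so chance cannot be excluded. That split set bacteria replicates 1 and 3 and replicates 1 and 2 of the combined treatment against the rest. So large a count points to a structure of these arrays, of unknown source. The split kept slides 1 and 4 whole and divided slides 2 and 3, while gill arrays of one slide did not deviate together (median r = -0.0161), and with slide as a block the real count was 29. Where the real count was 0, all 35 splits gave as many, which a count of 0 fixes, so these say nothing about chance. The highest counts were 253 for bacteria against control and 90 for bacteria with estradiol against estradiol in liver. In gill they were 1 for estradiol against control, 131 for bacteria against control and 0 for bacteria with estradiol against control and against estradiol. For the difference of the bacterial effect between tissues the highest count was 473. The splits with 253 and 473 exchanged control replicate 2 and bacteria replicate 2. In 100 of 100 draws each, the interactions (at most 456 in liver and 178 in gill) and sex (at most 1 in either tissue) reached the real count of 0, which is fixed in the same way.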

How the results depend on the processing

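Array weights and the fit without 2 gill arrays were added after the data were seen. All other alternatives were planned. Dim probes limit what can be seen: between 47.6% and 76.8% of probes were well above background on an array. Effects of the 28 named probe and comparison pairs kept their direction in all 664 combinations of a pair with a setting, and 653 stayed past the threshold. The other 11 were of EA_Msa_UN_113282 in gill, from an adjusted p of 0.0274 up to 0.130 (limma). These probes were chosen as the largest changes on the same arrays, so a kept direction was likely from the start. The combinations also count the replicate and slide blocks, which are the same fit, separately, and some leave out an array outside the comparison. The cause was not tested for any change below.

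With the scanner's log ratios, estradiol against control gave 2457 liver probes in place of 1464, and bacteria with estradiol against bacteria gave 10 gill probes in place of 44. With the value table these were 2491 and 13. In one fit over 32 arrays liver counts were 2467 for estradiol against control, 2509 for the combined treatment against control and 2027 against bacteria, and the combined treatment against control gave 1 gill probe in place of 0. That comparison gave 3 gill probes with Cy5 signal alone and 1 with sex as a covariate. Array weights gave 4570, 3429 and 3726 probes in these 3 liver comparisons, 9 for bacteria against control in liver, and in gill 38 for the combined treatment against control and 227 against bacteria. Without gill control replicate 4 and gill bacteria replicate 2 the last count was 56. Counts without the filter on dim probes stayed within 1.5 times. The scanner's ratios moved the median gill minus liver difference of all probes to 0.10, from -0.03.

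With the replicate number as a block, which is the same fit as slide as a block, liver counts were 1366 for estradiol against control, 1464 for the combined treatment against control and 1230 against bacteria. In gill the combined treatment against bacteria gave 29 in place of 44. The block gave 15280 probes for gill against liver, 741 and 652 for the differences of the estradiol and combined effects between tissues, and 0 in the other comparisons. Same-numbered arrays did not deviate together throughout. Correlations of their deviations ran from -0.394 to 0.466 in liver and from -0.288 to 0.279 in gill, and 5 of 16 arrays in each tissue correlated best with one of their own number.

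Leaving out each array gave in liver 894 to 2279 probes for estradiol against control, 1023 to 1849 for the combined treatment against control, 777 to 1745 for it against bacteria, 0 to 30 for bacteria against control, and 0 throughout for the combined treatment against estradiol and the interaction. In gill it gave 15 to 101 for the combined treatment against bacteria, 0 to 18 for it against control, 0 to 1 for bacteria against control, and 0 throughout for the other 3. Leaving out each fish gave 15089 to 15874 probes for gill against liver, 410 to 1091 and 447 to 992 for the differences of the estradiol and combined effects, and 0 for that of bacteria. The gene list alternatives were not run, since the probes carry no names. A difference within a fish spans a gill slide and a liver slide, so only the replicate number was fitted as a block there. The fit over 32 arrays does not apply to such differences, and the value table gives no gill minus liver level.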

Other observations

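The comparisons in this part were all chosen after the data were seen. Liver probes that estradiol lowered were mostly probes of liver rather than gill. Of 510 probes lower with bacteria and estradiol than with bacteria, 354 (69.4%) read at least 2-fold higher in liver than in gill of the 4 control fish, which are not part of that comparison. Of the 687 higher probes 158 (23.0%) did, and of 20161 probes not past the threshold 1814 (9.0%). The odds ratios against the last set were 22.9 and 3.02 (Fisher's exact test over probes, which are not independent replicates). The median gill minus liver difference in control fish was -2.69 for the lowered, -0.24 for the raised and -0.03 for the other probes. A probe must have signal in livers without estradiol to be found lower, and the sets were not matched on liver level. How much of the difference between the sets follows from this was not tested.

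Over both bacterial conditions together, 8 fish with estradiol against 8 without, estradiol moved 2827 liver probes (1591 higher and 1236 lower) and 34 gill probes (12 higher and 22 lower, limma). Of the 34 gill probes 33 were tested in liver, where 10 passed, all in the same direction. They made up 6 of 11 higher and 4 of 22 lower probes, where 7.45% of all tested liver probes passed as higher and 5.79% as lower. Both tissues come from the same fish, so the overlap is no independent test. Bacteria over both estradiol conditions gave 0 probes in liver (368 at an unadjusted p under 0.05) and 0 in gill (922, limma). Over the 2827 liver probes, the estradiol effect with bacteria minus that without, signed by the direction of the effect, had a median of -0.06 log2 units and quartiles of -0.31 and 0.17. The median size of the effect was 0.79. Whether estradiol acted differently by sex gave 0 liver probes with limma, while 1935 had an unadjusted p under 0.05 where 1068 would be expected by chance, and 0 gill probes (419). The liver arrays with the lowest quality weights, control replicate 2 (0.10) and estradiol replicate 4 (0.29), were both of males. They enter this comparison directly, and the count of 1935 without them was not tested, so it does not show a response that differs by sex.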
